A study of Mus musculus with 6 samples.

How the data were processed

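The series measured gene expression in total RNA of cells labelled EOMA, a mouse endothelioma cell line used as a model of vascular tumours. Cells were taken after 24 h with the solvent DMSO (3 libraries) or with 2 µM DHTS (3 libraries). DHTS is 15,16-dihydrotanshinone I, a tanshinone from the root of Salvia miltiorrhiza. Per the labels' protocols, RNA was taken with TRIzol, libraries were made with a NEBNext Ultra kit and sequenced on an Illumina HiSeq instrument under normoxic culture. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

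Per the submitters' processing notes, the authors used fastp 0.20.0, HISAT2 2.0.4, Cufflinks and Cuffdiff 2.2.1 with the mm10 build; the role of each tool and the annotation release are not given in the sources used here. The deposited table holds 22564 protein-coding genes with an FPKM value per library, which the authors scaled to gene length and library size. A second block of deposited columns, headed as counts, holds a signal: the values are estimated fragments divided by 1 factor per library. Between 92.7% and 93.0% of the values above 0 lay within 0.1 of a whole number of fragments once each library's factor was estimated, and 1525 of the 11416 tested genes (13.4%) held fractions shared with another gene. Because of these fractions no count model was fitted, and a test that models counting noise is not reported. The estimated fragments per library numbered 10230401, 9753768 and 12255261 with DMSO and 10415328, 11113851 and 9343157 with DHTS.

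Genes were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an empirical Bayes fit using the trend and robust options. Every fold change is therefore on the log2(FPKM + 1) scale, with a pseudocount of 1, and understates the change of low genes. Genes with a mean FPKM of at least 1 over the 6 libraries entered the fit, with treatment as the only term. Tests were two-sided, with Benjamini-Hochberg adjustment over the 11416 genes and a threshold of 0.05. Adjusted p-values of genes in the text are from this limma fit unless another test is named. SE is the moderated standard error of limma, and SD is taken over the 3 libraries of a group.

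The design, the alternatives, 30 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were tested with camera of limma at an inter-gene correlation of 0.01, with adjustment over 29 lists. Camera with a correlation estimated per list, and fry, were run beside it. Of the list entries, 925 were matched to a gene and 1 was not. The rule named the 8 genes with the largest rise and the 8 with the largest fall among calls with at least 5 FPKM in the higher group, no overlap between groups and a symbol that is not a model name. It further named 15 genes fixed in advance and up to 4 members of each list with the largest change past the threshold, or the 2 most highly expressed where no member passed. Genes named outside the rule are given as chosen after their values were seen.

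Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, limma without trend and robust, a threshold of 2-fold, a replicate block, and leaving out each library. A restriction to protein-coding genes was not run, since the table holds no other genes. Added after the data were seen were fits on the scaled fragments (mean of at least 10), without the genes of a chromosome 8 span listed at 0 in every DMSO library, and without genes holding fractional fragments. After the data were seen, pathways named in the deposited table, lists of marker genes of 10 tissues (1 gene of which is not reported here and was left out of its list), detection at equal depth, fragments of receptor genes drawn at random to the exon length of the chromosome 8 span and other splits of the 6 libraries were tested as well. A test of the change in fragments on olfactory and vomeronasal receptor genes, and 1 of an AU-rich motif in 3′ UTRs, were set down before their results were seen. Gene coordinates are from the GENCODE annotation of mm10, counted from 1.

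The fits were tested on simulated fragments drawn for the real genes at the real library sizes, a dispersion of 0.01 and 200 genes changed between the groups. Over the 11414 genes that passed the filter, 74.2% of the 66 genes changed 1.5-fold were recovered, 98.5% of 67 changed 2-fold and 100% of 65 changed 4-fold, and 13 of 193 calls were unchanged genes. The real fit called 5720 genes, far more than the 200 changed here, so these rates need not hold for it. Both simulated lists of changed genes were called by camera, and 0 of 30 lists of unchanged genes were. Genes were drawn independently of each other, and all members of a changed list moved in the same direction. The simulation therefore does not test list calls where genes are correlated, as in the real data (estimated at 0.335 for cytosolic ribosomal protein genes). Further steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The kit's strand setting is not given in the sources used here, so fragments of a gene and of an antisense partner cannot be told apart.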

Results

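RNA was sequenced from cells labelled EOMA, a mouse endothelioma line. They were treated for 24 h with DMSO (n = 3 libraries) or with 2 µM DHTS (n = 3 libraries). DHTS is 15,16-dihydrotanshinone I, a plant tanshinone. The series title places the comparison in work on infantile hemangioma and on hypoxia-inducible factor 1, the transcription factor that drives the response to low oxygen. Libraries held 9343157 to 12255261 estimated fragments on 22564 protein-coding genes, of which 11416 reached a mean of 1 FPKM and were tested. Libraries of a group correlated with each other at r = 0.986 to 0.989 across genes, and libraries of different groups at 0.929 to 0.932, where genes are not independent replicates. Each pair of libraries within a group differed by more than counting noise, with a chi-square per degree of freedom of 2.64 to 3.34.

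Genes that mark endothelial cells were mostly near 0 in all 6 libraries. Of 30 endothelial markers, 10 reached a mean of 1 FPKM, and 13 were listed at 0 in every DMSO library. Cdh5, the adhesion molecule of endothelial junctions, was listed at 0 in all DMSO libraries and at 0.0481, 0 and 0 FPKM with DHTS. Tie1, Emcn, Fli1, Icam2 and Clec14a were listed at 0 throughout. Pecam1 stood at 0.178 ± 0.0719 FPKM with DMSO, where the value after ± is the SD of 3 libraries here and in what follows. Cd34, a surface protein of endothelial and progenitor cells, stood at 77.6 ± 2.90 FPKM, the transcription factor Ets1 at 40.6 ± 1.33 and Egfl7 at 29.2 ± 2.65. Among 16 epithelial markers 11 reached a mean of 1 FPKM over the 6 libraries and 9 in DMSO cells, with Krt18 at 136 ± 2.79 FPKM and Elf3, Epcam and Spint1 between 20.3 and 34.9 FPKM. Cdh1, the epithelial cadherin, stood at 0.0319 ± 0.0324 FPKM in DMSO cells and Krt19 at 0.0824 ± 0.0872, and Krt14 and Cldn7 were listed at 0 there. Kdr, the main VEGF receptor, was listed at 0 in each DMSO library and at 0.0926, 0.0147 and 0 FPKM with DHTS. All other genes named here as markers were chosen after their values were seen.

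**Figure D1:**
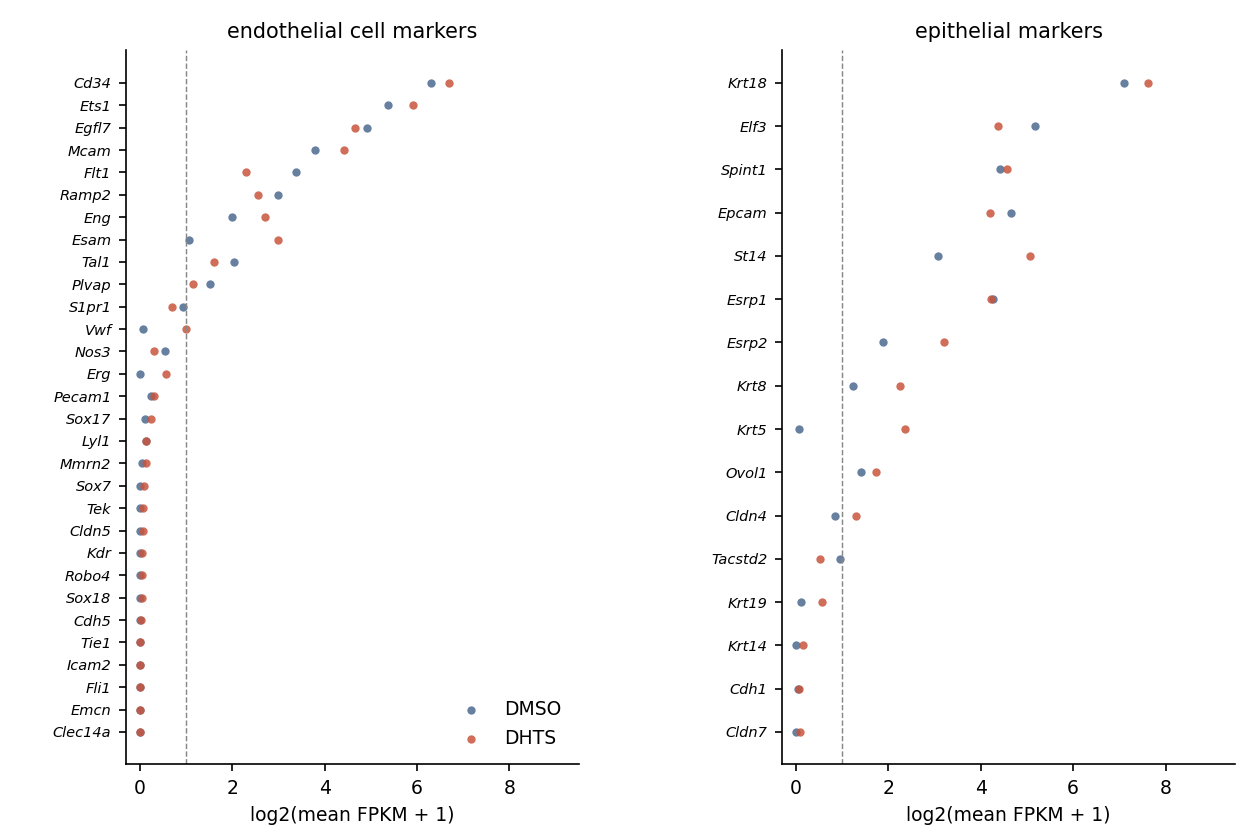
Mean expression of the endothelial (left) and epithelial (right) marker genes, as log2(mean FPKM + 1) over the 3 DMSO (blue) and 3 DHTS (red) libraries; the dashed line marks 1 FPKM. Of the 30 endothelial markers 10 had a mean of at least 1 FPKM over the 6 libraries, against 11 of the 16 epithelial markers.

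The comparison of DHTS with DMSO asked which transcripts the compound changed. DHTS-treated cells had 3218 genes higher and 2502 lower than DMSO cells (limma, adjusted p under 0.05), and 665 and 200 of these changed at least 2-fold. Groups did not overlap in 6828 genes (59.8% of those tested, where chance gives 10%). Quantile normalization gave 2551 genes higher and 3411 lower, so 56.3% of calls were higher in the fit as designed and 42.8% under that scaling, which lowered the median log2 fold change of all genes from 0.03 to −0.07.

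Among the largest rises were 2 carboxylesterases, Ces2e, which went from 0.0654 ± 0.0200 to 31.9 ± 1.29 FPKM (log2 fold change 4.95, SE 0.08, adjusted p = 3.5e-08), and Ces2g, which rose by 3.90. The matrix protein gene Matn4 rose by 4.77 (SE 0.07, adjusted p = 2.2e-08), the membrane-bound metalloproteinase gene Mmp15 by 4.35, the calcium-binding S100a8 by 4.33, the guidance receptor Robo3 by 4.02, the p53-regulated desmosome gene Perp by 3.94 and the lysosomal protein gene Cd68 by 3.76. Ces2e and Ces2g have similar sequences, so the split of fragments between them is uncertain. These 8 stand in for the 8 first named by the fixed rule, which all lie in one span of chromosome 8, and this replacement was chosen after the data were seen. Among the largest falls was that of Saa3, an acute-phase serum amyloid gene at chromosome 7, positions 46711998 to 46715700, which dropped from 2709 ± 160.2 to 351 ± 9.85 FPKM (log2 fold change −2.94, SE 0.05, adjusted p = 3.5e-08). Inmt (−2.98), Chac1 (−2.35), Fmo1 (−2.31), Ccl20 (−2.17), Mettl7b (−2.11) and Nupr1 (−2.11) fell as well. The histone gene Hist1h4k was listed at 0 in all DHTS libraries and at 11.5, 5.09 and 7.24 FPKM in the DMSO libraries.

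On chromosome 8, positions 119910360 to 124345724 (4.44 Mb), all 75 genes, which the deposited table places in a single merged locus, were listed at exactly 0 in each of the 3 DMSO libraries, while 65 were above 0 in every DHTS library. The span includes genes that every cell uses. The ribosomal protein gene Rpl13 was listed at 0 with DMSO and at 1214, 1200.0 and 1196 FPKM with DHTS. The respiratory chain gene Cox4i1 was listed at 0 with DMSO and at 915, 932 and 913 FPKM with DHTS. Cyba, Aprt, Map1lc3b, Tcf25, Emc8 and Trappc2l, the others first named by the rule, were listed at 0 with DMSO and at 54.8 to 320 FPKM with DHTS. The 52 tested genes of the span are all among the genes called higher, and all among the 665 that rose at least 2-fold. No 2-fold count without them is given. Without the span 3166 genes were higher and 2499 lower. No fold change is given for genes of the span.

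**Figure D2:**
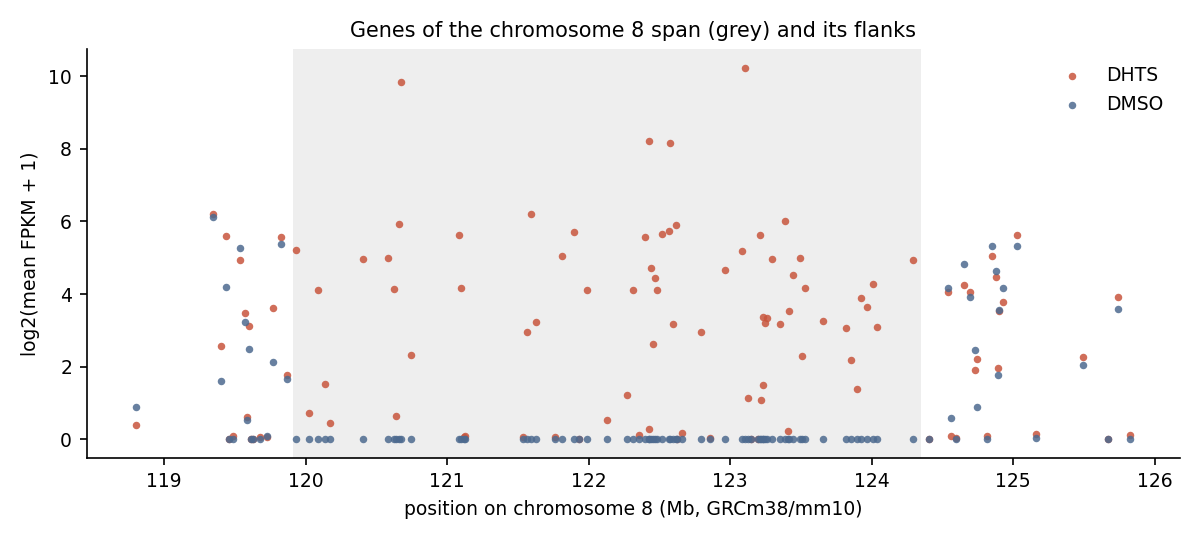
Mean expression, log2(mean FPKM + 1), of the genes along chromosome 8 (Mb) in DMSO (blue) and DHTS (red) libraries, with the span in grey. All 75 genes of the span lie at 0 in DMSO libraries, and genes on both sides are expressed in both groups.

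Of the 29 lists tested, 15 changed (camera, adjusted p under 0.05), 6 of them upward and 9 downward. With an estimated correlation 7 calls held: p53, NRF2, SREBP2, endoplasmic reticulum chaperones, glycolysis, HIF-1 targets and NF-kB. Their camera adjusted p then ran from 0.0223 (SREBP2) to 0.0483 (NRF2, HIF-1 targets and NF-kB), the latter close to the threshold. The glycolysis and HIF-1 lists share members, Slc2a1 and Pfkl among them, so these calls are not independent. Counts of changed members adjusted over the list alone equalled those over all genes tested in 20 of the 30 lists and are given for the other 10.

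**Figure D3:**
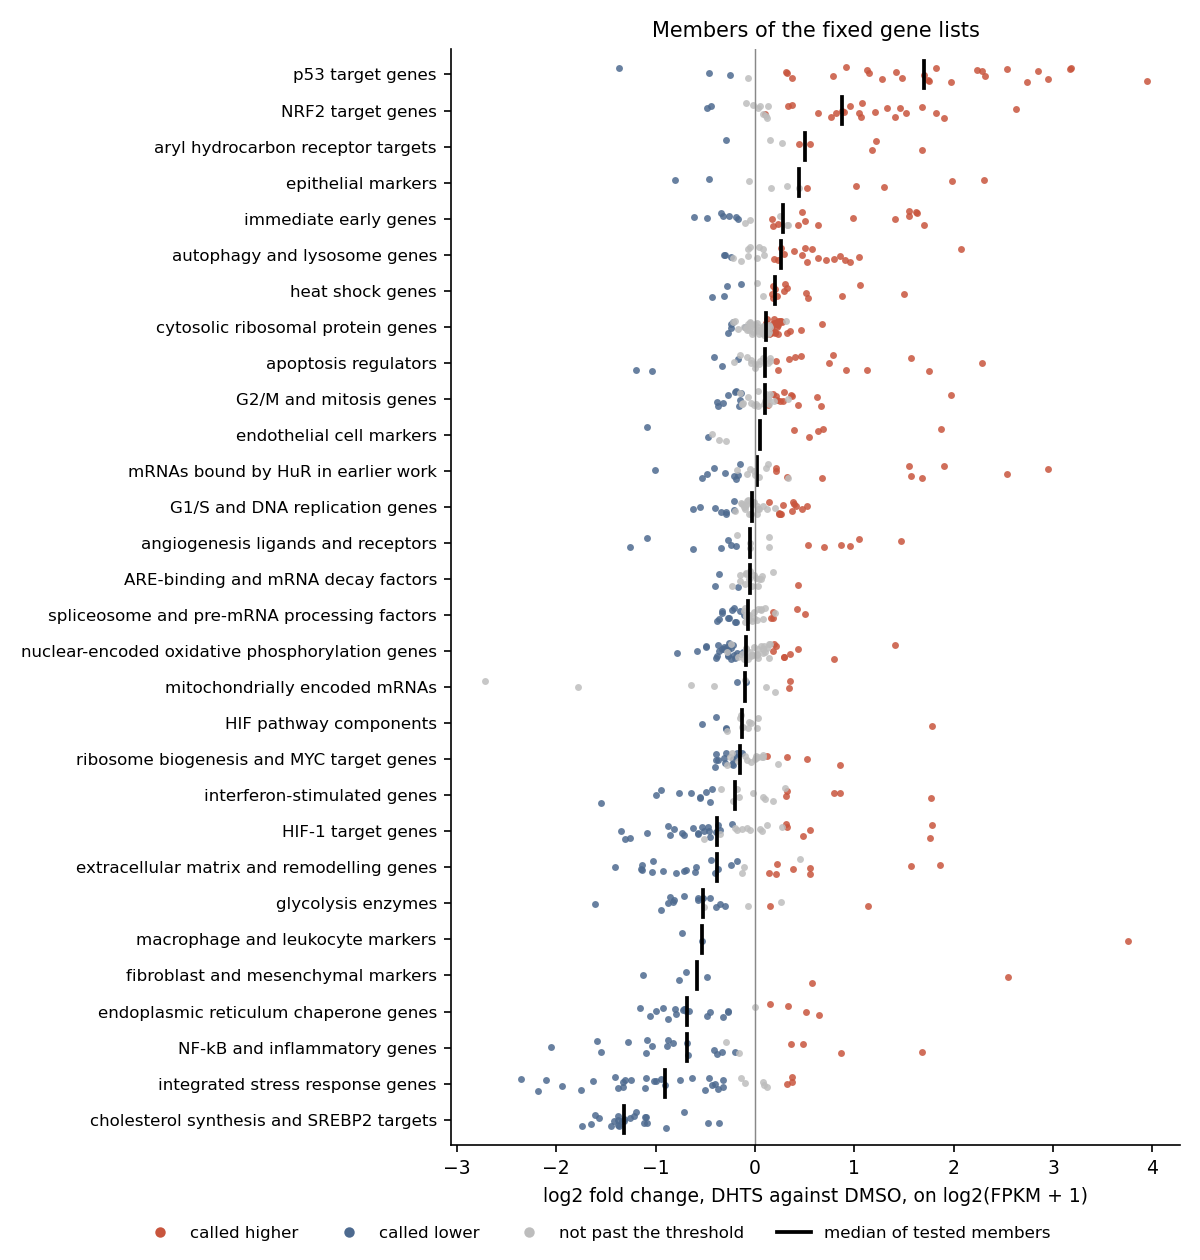
log2 fold change, DHTS against DMSO, of each tested member of the 30 gene lists, coloured by call, with the list's median as a black bar; genes of the chromosome 8 span are left out throughout, and points of genes at 0 in a whole group are not drawn. Medians run from −1.32 for cholesterol synthesis genes to 1.70 for p53 targets.

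Targets of p53, the tumour suppressor that halts damaged cells, rose as a group: 25 of 29 tested members were higher and 3 lower, with a median log2 fold change of 1.70 (camera adjusted p = 5.5e-11). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21 and lies on chromosome 17 at 29090976 to 29100727, rose from 62.0 ± 3.70 to 486 ± 1.38 FPKM (log2 fold change 2.95, SE 0.05, adjusted p = 3.5e-08). Mdm2, the ubiquitin ligase that limits p53, went from 61.2 ± 7.49 to 360 ± 5.32 FPKM, Trp53inp1 rose by 3.17 and Dcxr by 3.18. Gadd45a, Plk3 and Sesn1, the 3 members that fell, were picked out after their values were seen. Of 30 apoptosis regulators 12 were higher and 5 lower, among them the death receptor gene Fas (2.29), Pmaip1 (1.75) and Apaf1 (1.57), while Bmf fell by 1.20. The list as a whole did not pass (camera adjusted p = 0.105), though it did at a mean of at least 5 FPKM (0.0399, range over alternatives 0.0399 to 0.218).

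Neither cell cycle list passed. G2/M genes had 13 of 41 members higher and 9 lower (17 and 10 adjusted over the list alone; camera adjusted p = 0.461), with Gtse1, a p53 regulator, at 1.97, Cenpe at 0.67 and Cdc20 at 0.62. G1/S genes had 14 of 43 higher and 8 lower (15 and 8 adjusted over the list alone; camera adjusted p = 0.930), and 2 of the higher ones, Cdt1 and Gins2, belong to the span and were listed at 0 with DMSO. Cdt1 was at 53.2, 51.4 and 53.8 FPKM with DHTS and Gins2 at 29.0, 28.5 and 34.3 FPKM. Ung fell by 0.62 and Pold2 by 0.55. The list's median was −0.01 (−0.03 without the span) and its mean 0.26, which includes Cdt1 and Gins2 of the span. Ccnd1, the cyclin of early G1, rose from 35.9 ± 0.681 to 45.0 ± 2.24 FPKM (adjusted p = 0.0018), and Myc fell from 59.4 ± 2.88 to 42.3 ± 1.53 FPKM (adjusted p = 0.00028).

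NRF2 targets, which encode antioxidant and detoxifying enzymes, rose: 23 of 33 were higher and 2 lower, at a median of 0.88 (camera adjusted p = 1.5e-07). The heme-degrading enzyme gene Hmox1 went from 43.6 ± 2.51 to 165 ± 6.75 FPKM (log2 fold change 1.90, SE 0.05, adjusted p = 5.1e-07) and the quinone reductase gene Nqo1 from 8.58 ± 0.556 to 29.7 ± 1.99 FPKM (1.68, SE 0.07, adjusted p = 3.8e-06). Gsta4 rose by 2.62, while Gsta1 was listed at 0 with DMSO and at 10.6, 13.8 and 8.60 FPKM with DHTS. Its near-identical neighbour Gsta2 was listed at 0 and at 4.25, 6.74 and 10.8 FPKM, so their split is uncertain. Aryl hydrocarbon receptor targets had 5 of 8 tested members higher and 1 lower (camera adjusted p = 0.0144; adjusted p = 0.118 with an estimated correlation). Nqo1 is also on this list, with Cyp1b1 (1.21), Tiparp (1.18) and Nfe2l2, which encodes NRF2 itself (0.55). Cyp1a1, the classical target of that receptor, was not tested, being listed at 0 with DMSO and at 0.115, 0.358 and 0.257 FPKM with DHTS. Heat shock genes had 13 of 19 higher and 4 lower at a median of 0.21 (camera adjusted p = 0.0323; adjusted p = 0.13 with an estimated correlation). Cryab, a small heat shock protein gene, rose by 1.06, Hspa1b by 0.88, and Hspa1a went from 0.829 ± 0.190 to 4.15 ± 0.418 FPKM. The call was lost on scaled fragments (adjusted p = 0.0601, range over alternatives 0.00554 to 0.0601). Hspa1a and Hspa1b are near-identical copies and their separate values are uncertain.

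Hif1a, the oxygen-regulated subunit of HIF-1, on chromosome 12 at 73901375 to 73947530, fell from 82.0 ± 1.79 to 56.5 ± 2.71 FPKM (log2 fold change −0.53, SE 0.05, adjusted p = 9.3e-05). Its partner Arnt went from 38.0 ± 3.07 to 30.9 ± 2.46 FPKM (−0.29, adjusted p = 0.0215). That call was lost without DMSO replicate 2 (adjusted p = 0.0608), DMSO replicate 3 (0.0683) or DHTS replicate 1 (0.0592), over a range of 5.7e-07 to 0.0683. Epas1 (−0.15, adjusted p = 0.214), Vhl (−0.06, adjusted p = 0.657) and Elavl1 did not pass. Epas1 did under quantile normalization (0.0161, range 0.0161 to 0.424) and Vhl on scaled fragments (0.0382, range 0.0382 to 0.942). Elavl1, on chromosome 8 at 4285382 to 4325413, encodes HuR, a protein that binds AU-rich elements in mRNA, and stood at 18.5 ± 0.624 and 16.5 ± 0.547 FPKM (−0.15, SE 0.06, adjusted p = 0.0617). It passed under median-ratio scaling (adjusted p = 0.0266) and quantile normalization (0.00886) and on scaled fragments (0.00478), over a range of 0.00478 to 0.165. Of 15 HIF pathway components 1 was higher and 4 lower (camera adjusted p = 0.0712, and 0.0409 without a filter, range over alternatives 0.0409 to 0.106). Under quantile normalization 1 was higher and 9 lower. The gene that rose was Egln3, a prolyl hydroxylase that marks HIF for decay (1.79). Targets of HIF-1 fell as a group, with 21 of 38 lower and 6 higher at a median of −0.38 (camera adjusted p = 0.00024). Bnip3, a mitophagy receptor, fell by 1.35 (SE 0.11), Stc2 by 1.31 and the glucose transporter gene Slc2a1 by 0.35 (70.2 ± 2.86 to 54.7 ± 0.432 FPKM, adjusted p = 0.00046), while Egln3 and Adm (1.76) rose. Vegfa, the main angiogenic growth factor, stood at 47.7 ± 3.53 and 42.1 ± 3.59 FPKM and did not pass (−0.18, adjusted p = 0.0965). It did under quantile normalization (adjusted p = 0.0410), with a replicate block (0.0291), without DHTS replicate 2 (0.0326) and on scaled fragments (8.8e-06), over a range of 8.8e-06 to 0.256.

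**Figure D4:**
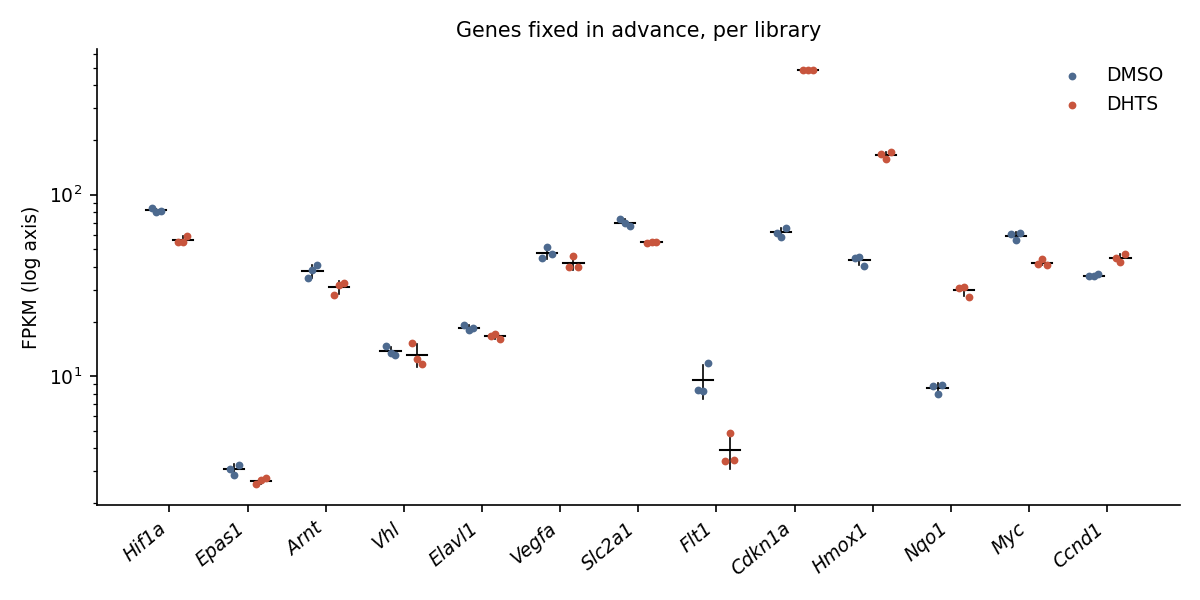
FPKM (log axis) of 13 genes fixed in advance in each DMSO (blue) and DHTS (red) library, with the mean and SD of the 3 libraries as black lines. Hif1a fell from 82.0 to 56.5 FPKM, and Cdkn1a rose from 62.0 to 486 FPKM.

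Enzymes of glycolysis fell, with 14 of 19 lower and 2 higher at a median of −0.52 (camera adjusted p = 4.1e-06). Aldoc fell by 1.61, Pfkl from 191 ± 4.94 to 104 ± 5.33 FPKM (−0.87, SE 0.05) and Pfkp by 0.95, though Pfkp holds fractional fragments, while Ldhb rose by 1.14. Gapdh was at 39.0, 42.9 and 800.5 FPKM in the DMSO libraries and at 296, 29.4 and 52.2 FPKM in the DHTS libraries, so its value is uncertain, and it was picked out after these values were seen. Angiogenesis ligands and receptors went both ways, with 6 of 18 higher and 7 lower (camera adjusted p = 0.828; median −0.05, mean 0.09). The VEGF receptor gene Flt1 fell from 9.48 ± 2.02 to 3.91 ± 0.818 FPKM (−1.09, SE 0.17, adjusted p = 0.0016) and Pdgfb by 1.26, while Nrp1, a VEGF co-receptor, rose by 1.47 and Jag2 by 1.04. Messenger RNAs bound by HuR in earlier work had 10 of 28 higher and 9 lower (10 and 10 adjusted over the list alone; camera adjusted p = 0.532). Cdkn1a, Mdm2, Hmox1 and Ptgs2 (1.68) rose most. The list's median of 0.02 turned to −0.02 under median-ratio scaling and −0.08 under quantile normalization. Factors that bind AU-rich elements or degrade mRNA had 1 of 20 higher (the deadenylase gene Parn, 0.44) and 3 lower, with Hnrnpd at −0.17 (camera adjusted p = 0.288). The Hnrnpd call was lost under quantile normalization (adjusted p = 0.13, range over alternatives 6.7e-06 to 0.13). Cnot1 and Cnot6, both subunits of a deadenylase complex and both with fractional fragments, were the other 2 that fell.

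Cholesterol synthesis and SREBP2 target genes fell together: 24 of 25 were lower, at a median of −1.31 (camera adjusted p = 3.9e-15). Cyp51, a sterol demethylase gene on chromosome 5 at 4081145 to 4104746, went from 85.2 ± 1.96 to 24.8 ± 0.391 FPKM (−1.74, SE 0.04, adjusted p = 2.2e-07). Fdps fell by 1.65 and the sterol sensor partner Insig1 by 1.61. The remaining member, Mvd, belongs to the chromosome 8 span and was listed at 0 with DMSO and at 26.0, 22.2 and 27.6 FPKM with DHTS.

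Genes of the integrated stress response, the amino acid and stress programme under ATF4, had 27 of 36 members lower and 4 higher (4 and 28 adjusted over the list alone) at a median of −0.83 (camera adjusted p = 9.3e-09; adjusted p = 0.0537 with an estimated correlation). Chac1, a glutathione-degrading enzyme gene, fell from 49.1 ± 3.77 to 8.88 ± 1.75 FPKM (−2.35, SE 0.13, adjusted p = 1.0e-05), the hormone gene Fgf21 by 2.18 and Nupr1 by 2.11. The amino acid transporter gene Slc7a5, in the span, was listed at 0 with DMSO and at 51.36, 52.97 and 49.88 FPKM with DHTS. Without it the median was −0.91. Endoplasmic reticulum chaperone genes fell in 17 of 22 cases and rose in 4, at a median of −0.68 (camera adjusted p = 2.2e-06). Hspa5, the chaperone BiP, went from 1287 ± 49.2 to 678 ± 18.5 FPKM (−0.92, SE 0.04, adjusted p = 2.1e-06), Herpud1 fell by 1.16 and Pdia6 by 1.00.

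Inflammatory genes regulated by NF-kB fell, with 16 of 22 lower and 4 higher at a median of −0.68 (camera adjusted p = 5.5e-06). The chemokine genes Ccl5 (−2.05) and Cxcl10 (−1.55) and the adhesion molecule gene Vcam1 (−1.59) were lower, and Ptgs2, the inducible cyclooxygenase, was higher. Interferon-stimulated genes had 5 of 24 higher and 10 lower (camera adjusted p = 0.0712, and 0.0168 without a filter and 0.0496 at a mean of at least 5 FPKM, range over alternatives 0.0168 to 0.0947). Among its members were Gbp3 at 1.77 and Parp14 at −0.95. Extracellular matrix genes had 17 of 28 lower and 8 higher at a median of −0.38 (camera adjusted p = 0.0104; adjusted p = 0.17 with an estimated correlation). That call was lost under quantile normalization (adjusted p = 0.0588, range over alternatives 0.00449 to 0.0588). Col5a1 fell from 16.8 ± 0.458 to 5.74 ± 0.165 FPKM (−1.40) and Tnc by 1.15, while the basement membrane gene Nid1 rose by 1.87 and the urokinase gene Plau by 1.57.

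Autophagy and lysosome genes had 18 of 30 higher and 3 lower (19 and 3 adjusted over the list alone) at a median of 0.28 (camera adjusted p = 0.0050; adjusted p = 0.0736 with an estimated correlation). The list holds Map1lc3b of the span, without which the median was 0.26. Ulk1, the kinase that starts autophagy, rose from 10.3 ± 0.663 to 46.9 ± 1.78 FPKM (2.08), Wipi1 by 1.04 and Atg14 by 0.96. Cytosolic ribosomal protein genes had 35 of 76 higher and 5 lower (36 and 5 adjusted over the list alone) at a median of 0.12 (camera adjusted p = 0.0092; adjusted p = 0.588 with an estimated correlation), with Rps19 at 0.67. Median-ratio scaling gave 27 higher and 8 lower. That call was lost on scaled fragments (adjusted p = 0.0545, range over alternatives 5.4e-05 to 0.0545), and many of these genes have processed copies elsewhere in the genome. Ribosome biogenesis genes had 13 of 32 lower and 4 higher (camera adjusted p = 0.0313; adjusted p = 0.118 with an estimated correlation), with Pes1 at −0.40 and Cad at 0.86. Spliceosome factors had 13 of 38 lower and 5 higher (camera adjusted p = 0.0323; adjusted p = 0.118 with an estimated correlation), with Srsf1 at −0.38 and Prpf8 at 0.42. The call for ribosome biogenesis was lost under quantile normalization (adjusted p = 0.0864) and without fractional-fragment genes (0.115), over a range of 0.00649 to 0.115. The call for spliceosome factors was lost in the same fits (0.477 and 0.0952), over a range of 0.00732 to 0.477, and median-ratio scaling gave 3 higher and 18 lower.

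Nuclear-encoded oxidative phosphorylation genes had 24 of 61 lower and 10 higher (11 higher and 24 lower adjusted over the list alone; camera adjusted p = 0.0561), with Ndufs8 at −0.78 and Ndufb6 at 1.41. Their median was −0.09 and their mean 0.10, which includes Cox4i1. Without the chromosome 8 span the list passed as lower (adjusted p = 0.0297), as it did in 9 of 16 alternatives in all, over a range of 0.0168 to 0.968. Quantile normalization gave 16 higher and 24 lower. Mitochondrially encoded mRNAs had 2 of 11 higher and 2 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.828), the former mt-Nd1 (0.35) and mt-Nd2 (0.34), which hold fractional fragments. Immediate early genes had 14 of 26 higher and 7 lower (15 and 7 adjusted over the list alone; camera adjusted p = 0.0754), passing under quantile normalization (0.0356, range over alternatives 0.0356 to 0.106). Among them were Btg2 at 1.70, Fosl1 at 1.63 and Dusp1 at 1.56.

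Markers of cell types were tested as lists too. Tested endothelial markers had 5 of 10 higher and 2 lower (camera adjusted p = 0.713), with Esam at 1.87 and Mcam at 0.63, and 5 higher and 4 lower under quantile normalization. Epithelial markers had 5 of 11 higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.110), among them the protease gene St14, from 7.45 ± 0.311 to 32.4 ± 0.830 FPKM (1.98), and Krt5, from 0.0399 ± 0.0692 to 4.12 ± 0.0189 FPKM (2.30). Fibroblast and mesenchymal markers had 2 of 6 higher and 4 lower (camera adjusted p = 0.306; median −0.58, mean 0.01), with Des at 2.55 and Pdgfrb at −1.13. Of the macrophage and leukocyte markers only 3 were expressed at the level tested and camera was not run: Cd68 rose, while Csf1r (−0.73) and Cd14 (−0.53) fell. Other tissue lists were written after values were seen, and their genes named here were picked out then. Of 14 genes of the kidney tubule list 8 were tested, 5 of them lower and 0 higher. Cdh16 fell from 46.6 ± 1.43 to 13.9 ± 0.485 FPKM, Bicc1, with fractional fragments, from 134 ± 4.01 to 71.1 ± 3.15, Lrp2 from 10.6 ± 0.556 to 2.26 ± 0.219, Emx2 from 9.31 ± 1.07 to 7.01 ± 0.304 and Pkhd1 from 5.00 ± 0.525 to 2.21 ± 0.223. Pax8 (64.5 ± 5.27 and 60.3 ± 2.33 FPKM, adjusted p = 0.269), Pax2 (adjusted p = 0.0991) and Lhx1 (adjusted p = 0.458) did not pass. No list test was run on these genes. Of 5 tested keratinocyte genes 4 were higher and 0 lower, among them Itgb4, with fractional fragments, from 4.58 ± 0.0520 to 21.1 ± 0.826 FPKM.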

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

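The fits on scaled fragments, without the chromosome 8 span and without genes holding fractional fragments were chosen after the data were seen. The counts of 3218 higher and 2502 lower genes stayed within 1.5 times under the pseudocount, filter, scaling and moderation alternatives (2551 to 3481 higher, 2273 to 3411 lower), and requiring 2-fold left 665 and 200 by construction. Leaving out 1 library gave 2853 to 2925 higher and 2176 to 2306 lower genes and 15 or 16 changed lists. The added fits gave 4050 higher and 3411 lower genes on scaled fragments, 3166 and 2499 without the span, and 2856 and 2241 without fractional-fragment genes. The replicate block gave 3053 higher and 2384 lower genes and 16 lists. Same-numbered libraries showed no sign of deviating together (correlations of −0.05, 0.06 and 0.01), against −0.08 to 0.08 for libraries of different numbers. With 3 libraries per group this cannot exclude that same-numbered libraries were paired. The count of 15 changed lists was 7 with an estimated correlation and 28 with fry, and 13 to 18 otherwise. Fry asks whether a list's genes move on balance and not whether they differ from other genes. It turned the direction of the angiogenesis and the oxidative phosphorylation lists (both fry adjusted p = 0.0020). Without passing, it also turned that of mitochondrially encoded mRNAs (fry adjusted p = 0.328). The cause was not tested, but the oxidative phosphorylation list holds Cox4i1 of the chromosome 8 span, and fry was not run without that gene. A restriction to protein-coding genes was not run, as the table holds no others. Depth limits low genes: those under a mean of 1 FPKM were not tested, and 6380 were listed at 0 in all 6 libraries.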

Other observations

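The tests of pathways, of the chromosome 8 span, of endothelial and other tissue markers, of library depth in detection, and of other splits of the samples were chosen only after the result was seen, as were the genes named with them. Pathways named in the deposited table were tested with camera on the 11364 genes outside the span, and 3 of 262 were higher and 18 lower. Arachidonic acid metabolism, the source of prostaglandins, had 13 of 23 genes higher and 0 lower (camera adjusted p = 0.0229; 0.400 with an estimated correlation), among them the prostaglandin synthase gene Ptges (log2 fold change 2.48, SE 0.11, 0.643 to 8.17 FPKM) and Ptgs2 (1.68). Biosynthesis of unsaturated fatty acids had 10 of 17 lower and 4 higher (camera adjusted p = 0.010; 0.400 with an estimated correlation): the desaturase genes Scd1 (175.7 to 52.1 FPKM, −1.74) and Scd2 (−1.74) and the elongase gene Elovl6 (−1.59, with fractional fragments) fell, while the peroxisomal genes Acaa1b (1.91) and Acox3 (1.58) rose. Aminoacyl-tRNA biosynthesis had 19 of 43 lower and 5 higher (camera adjusted p = 0.0074; 0.400 with an estimated correlation), with Tars at −0.97 and Nars at −0.87. With an estimated correlation 0 of the 262 pathways passed in camera (lowest adjusted p = 0.400), and 29 had an unadjusted p under 0.05.

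The 75 genes of the chromosome 8 span, listed at 0 in all DMSO libraries, form a single merged locus of the deposited table. Of the 10 nearest genes outside that locus with at least 1 FPKM in DHTS libraries, 5 on each side, 0 were at exactly 0 in all DMSO libraries, as had been seen beforehand. The span nearly matches a gene model of the merged locus, Gm20388 (positions 119910841 to 124345722). A deletion already in the cells before treatment would leave the span at 0 with DHTS too. As 65 of its genes were above 0 in every DHTS library, these values argue against such a deletion. This count cannot separate a missing estimate for the span in the DMSO libraries from a deletion with the same ends in DMSO cells alone. The ends of the latter would have to lie in the gaps to the nearest of the 10 outside genes. These were Klhl36, 33365 bp before the span, and Cog2, 175043 bp after it. That deletion would take out Rpl13 and Cox4i1. Silencing cannot be told apart either. Of 29 genes elsewhere that were raised at least 8-fold on log2(FPKM + 1), only 2 were at 0 in all DMSO libraries. That cut can miss genes at 0 with DMSO that are low with DHTS, so the count decides nothing. Outside the span, 4 genes were at 0 in all DMSO libraries with a mean of at least 5 FPKM in DHTS. Sets of silent olfactory and vomeronasal receptor genes (1298 with annotated exons) were drawn to the exon length of the span. They held no fragment in any DMSO library in 31.1% of 10000 draws. Only 2.30 fragments were expected on that length, so these draws cannot decide on silencing.

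Another pattern was the low level of most endothelial transcripts in libraries labelled as an endothelioma line. Estimates that failed in all 6 libraries are not the whole cause, since 15 of the 20 markers under the tested level held a fragment in at least 1 library. Of these 20, 7 held a fragment with DMSO and 8 with DHTS alone. For the 13 without one with DMSO, failed estimates in the DMSO libraries cannot be told apart as a source of the DMSO zeros. Such a failure would not explain their DHTS means, which ran from 0 (Tie1, Emcn, Fli1, Icam2 and Clec14a) to 0.482 FPKM (Erg). Cells of another type may be the source: of 10 other tissue lists, written after some of their kidney genes had been seen, only the kidney tubule lineage list had a larger share of genes at 1 FPKM in DMSO libraries than the endothelial list (8 of 14, 57.1%, against 10 of 30, 33.3%), with Bicc1 at 134 ± 4.01, Pax8 at 64.5 ± 5.27 and Cdh16 at 46.6 ± 1.43 FPKM (SD, n = 3). That difference did not pass (two-sided Fisher's exact test, adjusted p = 0.383 over 10 lists). A share of genes at 1 FPKM depends on which genes were listed, so this test cannot decide cell identity. The bound that would have counted against cells of another type was also rewritten after a p for this comparison had been seen. That explanation therefore stays open. Mature nephron genes reached 3 of 15 and the remaining lists 0% to 26.7%, and Hnf4a of the kidney list is also on the hepatocyte list. The epithelial list, fixed in advance, was not in this comparison and was not tested against the endothelial list. Of its 16 members, 9 reached a mean of 1 FPKM in DMSO libraries.

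In detection, DHTS libraries held fragments on more genes (14490 ± 122 against 13652 ± 95.9, SD, n = 3). Thinning each library to 9343157 fragments left a difference of 841 genes with no overlap between groups, which argues against depth. The chromosome 8 span holds 75 genes, fewer than this difference. Fragments on 1427 olfactory and vomeronasal receptor genes numbered 47, 53 and 54 with DHTS and 15, 15 and 14 with DMSO, 3.63 times as many per fragment sequenced, consistent with more background reads such as genomic DNA. Transcription of normally silent genes after treatment could raise the same fragments and was not tested apart from it. After thinning, genes with at least 5 fragments numbered 12578, 12575 and 12593 with DHTS and 12138, 12142 and 12117 with DMSO. With only 47 to 54 fragments over 1427 receptor genes, these counts argue against background as the main source of that part of the difference. An exact two-sided test of 3 against 3 libraries cannot give a p under 0.1.

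A hypothesis, set down before its result was seen, was that mRNAs with AU-rich elements fell as a class by at least 0.1. The motif TATTTAT was sought in the longest annotated 3′ UTR of 11051 genes (97.2% of the 11364 tested outside the span). Within 10 bins of UTR length, the 3373 genes with the motif differed from the 7678 without it by −0.00964 in mean log2 fold change (two-sided permutation p = 0.438, 10000 permutations across genes, which are not independent replicates), which argues against such a fall. Hif1a itself carries 3 sites.

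The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 3218 higher genes, 2502 lower genes and 15 lists, the highest of the other splits gave 0, 1 and 9, and 1 of the 10 splits, the real one, reached each real value. Every other split mixes both treatments on each side, so the treatment difference adds to the spread within groups. Few gene calls there follow by construction. Those splits also keep part of the treatment difference, so their lists do not give a rate of false calls.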
